A study of Mus musculus with 9 samples.

How the data were processed

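The study measured gene expression by bulk RNA sequencing in mouse hearts after a sham operation, 7 d after ligation of the left anterior descending artery and 28 d after it, with 3 mice in each of the 3 groups. The groups and replicate numbers were taken from the sample titles. Per the labels' protocols, libraries were made from total RNA with the KAPA RNA HyperPrep kit. Reads were processed with Trim Galore (adapter trimming), STAR (alignment), featureCounts (counting) and the mm10 genome build, per the submitters' processing notes, which name these without a version. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The values analysed here are the counts deposited by the authors, whole-number read counts per gene symbol that were not normalized. Of 24964 symbols 24345 matched a RefSeq gene symbol, and 5629 symbols had 0 counts in all 9 libraries. Reads were not re-aligned, and other material of the study was not analysed here.

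Totals lay between 12351525 and 19238101 counts. Counts of the 3 sham libraries differed by more than sampling noise, with a chi-square of 1.67 to 1.8 times its degrees of freedom, so none was taken as a second deposit of another. Library preparation alone can give such an excess, and all 9 libraries were kept as replicates because the study's design gives 3 mice in each group. Intervals and floors cover counting error only. Coordinates were taken from the RefSeq annotation of GRCm38.

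Tests used R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 14347, and scaled by TMM. Factors were 0.869 to 0.881 in sham libraries, 1.08 to 1.12 at 7 d and 0.985 to 1.1 at 28 d. A means model with 1 coefficient per group was fitted to all 9 libraries, and each of the 3 comparisons was tested by the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. Fold changes were those fitted by this model, with a standard error taken as the absolute log2 fold change over the square root of F. Principal components used log2 CPM with a prior count of 2. "Rose", "fell" and "passed" refer to this threshold. A ratio against a group with 0 counts was bounded by a floor of 3 counts over the group. Ratios of counts are followed by their 95% counting interval.

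Before the data were examined, 54 gene lists were written from textbook knowledge with 1100 entries, of which 1079 were found and 1010 tested. Of these lists 52 were tested and the other 2 had under 3 tested members. Lists were tested by camera of limma 3.58.1 with a preset correlation of 0.01, again with a correlation estimated from the data, and by fry. The rule for named genes was fixed at the same time. It took 13 markers in each comparison, the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 1 log2 CPM and no overlap between the groups (symbols of the Gm and Rik forms left out), and for each list up to 4 members in its main direction and 2 in the other. Lists called by camera or with at least a fraction of 0.33 of their members past the threshold were to be described and the others given as counts. Only part of the genes that the rule names for the lists is printed. These examples were picked after their values were seen, at first with a preference for genes that were stable when a library was left out, and lists not called by camera are mostly given as counts. Members that moved against a list are named where there was 1, except a few members that are not reported here. Genes outside the rule are said to be so where they are named.

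The script was tested on simulated counts for the 14347 genes, with 100 genes changed by 2-fold and 100 by 4-fold. At 7 d against sham it called 64% and 87% of them with 17 false calls among 14121 unchanged genes, at 28 d against sham 71% and 92% with 13, and at 28 d against 7 d 70.0% and 88% with 11. All called changed genes had the right direction, and the list spiked into each comparison was called higher with 0 of 51 others.

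Alternatives planned before the data were examined were DESeq2 1.42.0, DESeq2-type size factors, library size alone, no filter, a stricter filter (1 CPM in 3 libraries and a mean of 2 CPM), fits of only the libraries compared, the replicate number as a block, an added threshold of 2-fold, an estimated correlation, fry and leaving out each library in turn. TMM without mitochondrial and haemoglobin genes was also planned, but removed 0 tested genes and so tested nothing. Further alternatives were chosen after seeing the data: leaving out the 3 libraries with over 100 CPM of Adipoq (Adipoq-rich libraries), summing the sham libraries to 1, because they differed so little (biological coefficient of variation 2.76%, against 17% at 7 d and 24.1% at 28 d), and limma voom with group weights. The labels give no batch, no time of day and no harvest time of the sham hearts, so none of these entered a fit.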

Results

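RNA was sequenced in bulk from the hearts of 9 male C57BL/6 mice, and the deposited table gives a read count per gene for each heart. In 6 mice the left anterior descending coronary artery was tied off, which stops the blood supply to part of the left ventricle and causes a myocardial infarction (MI). Of these hearts, 3 were taken 7 d and 3 were taken 28 d after the operation. The other 3 mice had a sham operation. The labels give 8 weeks as the age of the mice, give the tissue only as heart, and leave open when after surgery the sham hearts were taken. The counts summed to 12351525 to 13629120 in the sham libraries, 18355720 to 19238101 at 7 d and 15300344 to 15770389 at 28 d, and between 16059 and 17299 genes had at least 1 count in a library. The 10 most abundant genes took 13.6 to 13.9% of the counts in sham hearts, 8.3 to 10.1% at 7 d and 8.46 to 10.6% at 28 d. Levels are CPM, counts relative to the TMM-scaled library total, as means ± SD (n = 3 libraries). Log2 fold changes (log2 FC) are given ± their standard error. On the first principal component, with 74% of the variance, the 28 d libraries lay between the sham and the 7 d libraries.

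The 13 markers fixed before the data were examined are annotated as protein-coding genes, and the counts are over whole genes. On the mouse GRCm38 (mm10) assembly Nppa lies on chromosome 4 at 148000722-148002074, Nppb on 4 at 147985786-147987205, Myh6 on 14 at 54941921-54968017 and Myh7 on 14 at 54970684-54994626. Acta1 lies on chromosome 8 at 123891758-123894775, Atp2a2 on 5 at 122453513-122502225, Col1a1 on 11 at 94936224-94953042, Col3a1 on 1 at 45311538-45349706 and Postn on 3 at 54359267-54391041. Acta2 lies on chromosome 19 at 34240336-34255585, Cd68 on 11 at 69664213-69666170, Mki67 on 7 at 135689784-135716450 and Ppargc1a on 5 at 51454249-52115853.

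The comparison of hearts at 7 d with sham hearts asks which genes differ a week after the artery was tied. At 7 d 24 of 26 genes for fibrillar collagens and fibril assembly and all 26 monocyte and macrophage markers were higher than in sham hearts. Of the adult sarcomere genes 29 of 30 were lower, as were all 50 genes of the respiratory chain and ATP synthase. Col1a1, a chain of the main fibrillar collagen of scar, rose from 342 ± 9.9 to 11892 ± 2014 CPM (log2 FC 5.12 ± 0.22). Postn, a matrix protein of activated fibroblasts, rose 40.4-fold, Col3a1 rose 23.9-fold, and Cd68, a macrophage lysosomal protein, rose 19.4-fold. Myh6, the main myosin heavy chain of the adult mouse ventricle, fell from 43157 ± 1606 to 4469.9 ± 891 CPM (log2 FC -3.27 ± 0.29). Nppa, which encodes the natriuretic peptide ANP, rose 18.3-fold. Nppb, which encodes the related peptide BNP, stood at 388 ± 13.8 CPM in sham hearts and 389 ± 11 CPM at 7 d and did not pass the test (edgeR adjusted p = 0.971). Nppb passed with library size alone as the scaling, with a log2 FC of 0.34 and an edgeR adjusted p of 0.00737.

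**Figure D1:**
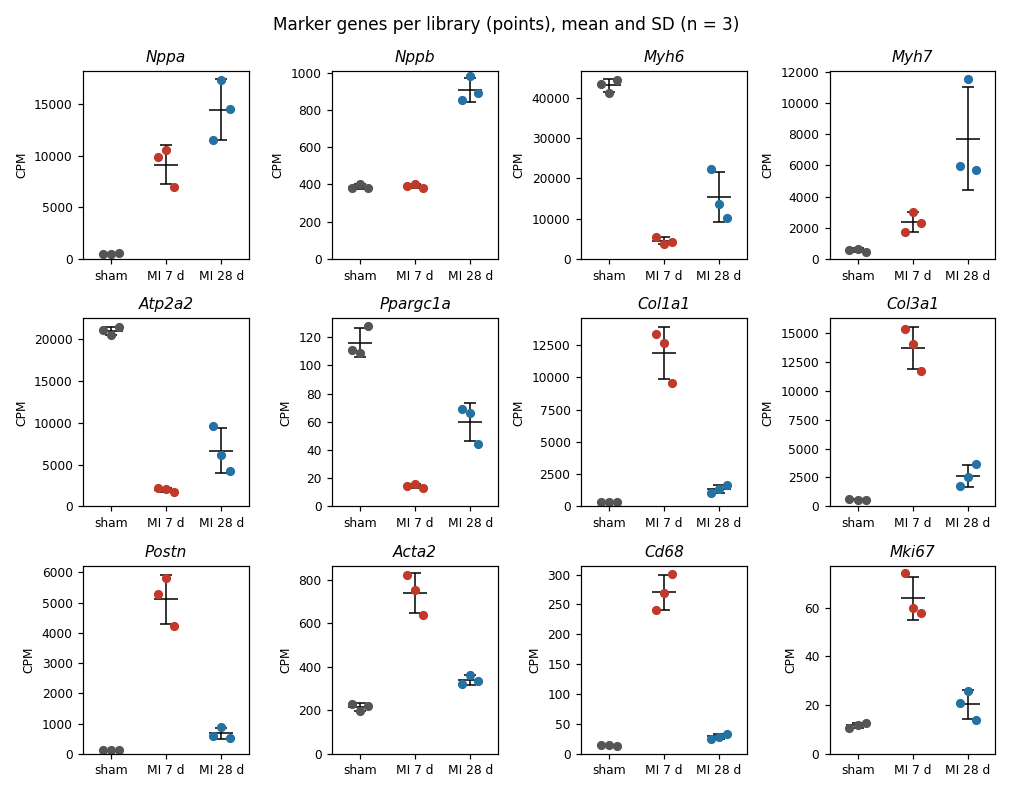
CPM (linear axes) of marker genes in sham, MI 7 d and MI 28 d hearts. Points are single libraries and bars the mean and SD of 3. Col1a1 stood at 11892 CPM at 7 d and 1335 CPM at 28 d, and Nppb at 388, 389 and 908 CPM in the 3 groups.

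Of the genes for fibrillar collagens and fibril assembly, 24 of 26 rose and 1 fell (P4ha2, log2 FC -0.24), 24 and 1 adjusted over the list alone, camera adjusted p = 2.23e-20, adjusted p = 0.133 with an estimated correlation. For P4ha2, library size alone gave a log2 FC of 0.0956 (edgeR adjusted p = 0.279). Col11a1 rose 102-fold and the small proteoglycan gene Fmod 62.6-fold. Of the collagen cross-linking enzymes all 7 rose (7 adjusted over the list alone, camera adjusted p = 1.4e-09, adjusted p = 0.133 with an estimated correlation). Lox, whose product starts the cross-linking of collagen, went from 19.4 ± 0.827 to 1241 ± 206 CPM. Among matrix proteases and their inhibitors 17 of 25 rose and 3 fell (17 and 3 adjusted over the list alone, camera adjusted p = 2.42e-06, adjusted p = 0.133 with an estimated correlation). Mmp12, the macrophage elastase, rose 54.4-fold and Timp1 29.7-fold, while Timp4 fell 12.1-fold. Of the markers of activated fibroblasts 19 of 20 rose and 1 fell (Lrrc15, log2 FC -2.13), 19 and 1 adjusted over the list alone, camera adjusted p = 3.7e-17, adjusted p = 0.133 with an estimated correlation. Cthrc1 rose 94.3-fold, Tnc 47.4-fold and the smooth muscle actin gene Acta2 3.42-fold. P4ha2 did not pass without sham replicates 1 or 3 or MI 7 d replicate 3 (log2 FC -0.21, -0.22 and -0.18, edgeR adjusted p = 0.0623, 0.0544 and 0.0759).

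Among cartilage-like genes of late scar fibroblasts 10 of 13 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 2.43e-05, adjusted p = 0.233 with an estimated correlation). Acan, which encodes aggrecan, rose 75.9-fold, and Cytl1 fell 3.0-fold. Of the resting fibroblast markers 10 of 17 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0207, adjusted p = 0.347 with an estimated correlation). Mgp rose 9.5-fold and Gsn fell 2.01-fold. In TGF-beta signalling 17 of 20 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 4.9e-08, adjusted p = 0.185 with an estimated correlation). Of the Wnt signalling genes 11 of 19 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.000503, adjusted p = 0.251 with an estimated correlation). Sfrp2, a secreted Wnt modulator, rose 65.1-fold. For basement membrane genes 11 of 16 rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0436, adjusted p = 0.42 with an estimated correlation). Of the senescence and secretory genes 13 of 14 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 5.12e-07, adjusted p = 0.161 with an estimated correlation). Cdkn2b, a cell cycle inhibitor, rose 19-fold. Cytl1 did not pass with voom (adjusted p 0.0532).

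Of the monocyte and macrophage markers all 26 rose (26 adjusted over the list alone, camera adjusted p = 2.79e-30, adjusted p = 0.113 with an estimated correlation). Spp1, which encodes osteopontin, rose from 4.79 ± 0.574 to 425 ± 64.9 CPM, Gpnmb from 8.92 ± 1.14 to 730.0 ± 153 CPM, and Trem2 38.6-fold. Of the genes of antigen presentation on MHC class II all 10 rose (10 adjusted over the list alone, camera adjusted p = 1.89e-06, adjusted p = 0.222 with an estimated correlation). Cd74, the invariant chain, was 4.96-fold higher. Among T and NK cell genes 20 of 22 rose and 1 fell (Ctla4, log2 FC -3.33), 20 and 1 adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.251 with an estimated correlation. In the complement list 16 of 20 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 2.43e-05, adjusted p = 0.295 with an estimated correlation). Among interferon-stimulated genes 23 of 26 rose and 1 fell (Rsad2, log2 FC -0.87), 23 and 1 adjusted over the list alone, camera adjusted p = 0.000943, adjusted p = 0.222 with an estimated correlation.

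Of the chemokine and cytokine genes 24 of 31 rose and 2 fell (25 and 2 adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.233 with an estimated correlation). Ccl3 rose 28.3-fold. Among inflammasome genes 11 of 12 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 0.00194, adjusted p = 0.222 with an estimated correlation). Of the lysosome and autophagy genes 18 of 26 rose and 5 fell (18 and 5 adjusted over the list alone, camera adjusted p = 9.63e-08, adjusted p = 0.113 with an estimated correlation). The protease gene Ctsk rose 14.6-fold. For apoptosis and necroptosis 20 of 22 rose and 0 fell (20 and 0 adjusted over the list alone, camera adjusted p = 7.42e-05, adjusted p = 0.226 with an estimated correlation). In oxidative stress and ferroptosis 15 of 26 rose and 7 fell (15 and 7 adjusted over the list alone, camera adjusted p = 0.00169, adjusted p = 0.134 with an estimated correlation), where the haem oxygenase gene Hmox1 rose 11-fold and the mitochondrial superoxide dismutase gene Sod2 fell 8.14-fold. In the cell cycle list 35 of 40 rose and 4 fell (35 and 4 adjusted over the list alone, camera adjusted p = 1.89e-06, adjusted p = 0.354 with an estimated correlation). The proliferation marker Mki67 rose 5.47-fold and the mitotic kinase gene Cdk1 8.51-fold, while the G1 cyclin gene Ccnd1 fell 2.45-fold.

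In the adult sarcomere list 0 of 30 rose and 29 fell (0 and 29 adjusted over the list alone, camera adjusted p = 3.45e-14, adjusted p = 0.251 with an estimated correlation). Tnni3, the cardiac troponin I gene, went from 5359 ± 46.3 to 435 ± 86.9 CPM, and the creatine kinase gene Ckm fell 31.2-fold. Of the calcium handling genes 2 of 20 rose and 18 fell (2 and 18 adjusted over the list alone, camera adjusted p = 1.49e-06, adjusted p = 0.251 with an estimated correlation). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 21008 ± 515 to 1973 ± 252 CPM and its inhibitor Pln fell 6.52-fold. Among ion channel and gap junction genes 2 of 24 rose and 21 fell (2 and 21 adjusted over the list alone, camera adjusted p = 4.9e-08, adjusted p = 0.251 with an estimated correlation). The potassium channel subunit gene Kcnip2 was 28.2-fold lower. For adrenergic and cyclic AMP signalling 1 of 16 rose and 11 fell (Grk5, log2 FC 0.93), 1 and 11 adjusted over the list alone, camera adjusted p = 0.000968, adjusted p = 0.29 with an estimated correlation. In the fetal and wall stress programme 15 of 19 rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 1.88e-05, adjusted p = 0.222 with an estimated correlation). Sprr1a rose from 1.21 to 149.5 CPM and Myh7, the slow myosin heavy chain of the fetal ventricle, 4.13-fold. The skeletal actin gene Acta1 fell 5.39-fold.

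Of the nuclear-encoded genes of the respiratory chain and ATP synthase all 50 fell (50 adjusted over the list alone, camera adjusted p = 1.58e-28, adjusted p = 0.24 with an estimated correlation). Cox7a1, a cytochrome oxidase subunit of heart and muscle, went from 719 ± 46.2 to 34.7 ± 5.83 CPM. In the TCA cycle and pyruvate dehydrogenase list all 23 fell (23 adjusted over the list alone, camera adjusted p = 1.97e-17, adjusted p = 0.233 with an estimated correlation). Idh2 was 11.6-fold lower. For fatty acid oxidation 1 of 31 rose and 30 fell (Cpt1a, log2 FC 0.74), 1 and 30 adjusted over the list alone, camera adjusted p = 1.35e-16, adjusted p = 0.233 with an estimated correlation. Acaa2 fell 14.9-fold. In branched-chain amino acid and ketone catabolism all 21 fell (21 adjusted over the list alone, camera adjusted p = 3.86e-12, adjusted p = 0.251 with an estimated correlation). The ketone enzyme gene Bdh1 was 10.2-fold lower. Among PPAR and PGC-1 regulators 3 of 18 rose and 13 fell (3 and 13 adjusted over the list alone, camera adjusted p = 1.82e-05, adjusted p = 0.233 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial biogenesis, fell 7.97-fold. In glycolysis and glucose uptake 7 of 25 rose and 17 fell (7 and 17 adjusted over the list alone, camera adjusted p = 0.00745, adjusted p = 0.428 with an estimated correlation). The insulin-responsive glucose transporter gene Slc2a4 fell 8.67-fold and the lactate exporter gene Slc16a3 rose 13.7-fold.

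Of the endothelial markers 0 of 24 rose and 15 fell (0 and 15 adjusted over the list alone, camera adjusted p = 0.00745, adjusted p = 0.535 with an estimated correlation). Kdr, the main VEGF receptor gene, fell 6.43-fold and the fatty acid transporter gene Cd36 6.01-fold. For hypoxia and angiogenesis 7 of 23 rose and 11 fell (7 and 11 adjusted over the list alone, camera adjusted p = 0.198), against 10 higher and 8 lower with library size alone, where the median was -0.082. Vegfa was 4.83-fold lower and Vegfd 17.1-fold higher. Among epicardial and mesothelial markers 10 of 13 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.0452, adjusted p = 0.586 with an estimated correlation). Upk3b went from 0.549 ± 0.33 to 22.6 ± 21.4 CPM (log2 FC 5.33 ± 1.64). Of the cytosolic ribosomal protein genes 37 of 39 rose and 1 fell (Rps2, log2 FC -0.33), 37 and 1 adjusted over the list alone, camera adjusted p = 2.51e-05, adjusted p = 0.529 with an estimated correlation, with a median log2 FC of 0.73. For Rps2, library size alone gave a log2 FC of 0.00011 (edgeR adjusted p = 0.999). In the circadian clock list 8 of 19 rose and 7 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.475), with a median log2 FC of 0.13, a mean of -0.20 and a camera direction of down. Dbp, a clock output gene, rose 5.11-fold and Hlf fell 3.99-fold. Rps2 did not pass without sham replicate 2 or MI 7 d replicates 2 or 3 (log2 FC -0.31, -0.27 and -0.30, edgeR adjusted p = 0.054, 0.0699 and 0.0651). Upk3b did not pass without sham replicates 1 or 2 or MI 7 d replicate 3 (log2 FC 5.09, 5.12 and 4.24, edgeR adjusted p = 0.0616, 0.0567 and 0.0509), nor with voom (adjusted p 0.0869). Upk3b had a log2 FC of 5.95 without sham replicate 3. Upk3b had a log2 FC of 4.23 without Adipoq-rich libraries.

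**Figure D2:**
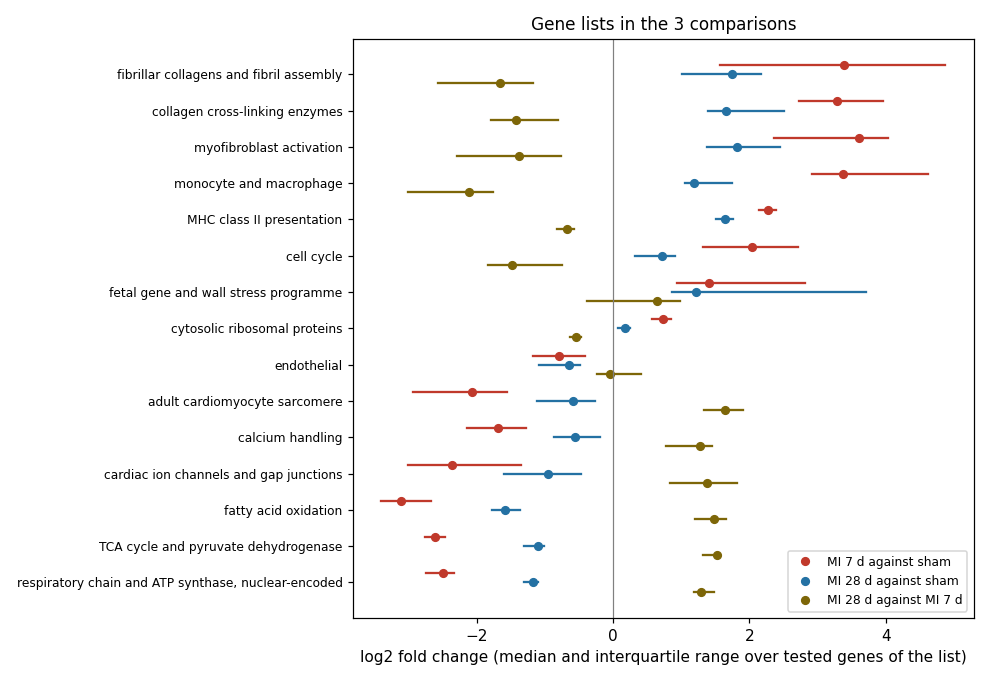
Median (point) and interquartile range (line) over the tested genes of 15 lists of the log2 FC in the 3 comparisons, with TMM scaling. Collagen genes had a median of 3.38 at 7 d and 1.75 at 28 d against sham and respiratory chain genes -2.5 and -1.17.

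Camera did not call the other lists at 7 d against sham. Genes higher and lower are given for each, with those adjusted over the list alone in parentheses. They were 3 and 0 of 13 in the resident macrophage list (3 and 0, camera adjusted p = 0.598, without Adipoq-rich libraries 3 and 5 of 11, median -0.53, not 0.32) and 5 and 0 of 10 in the neutrophil list (4 and 0, camera adjusted p = 0.0712). Genes higher and lower were 6 and 0 of 13 in the B and plasma cell list (4 and 0, camera adjusted p = 0.475, without Adipoq-rich libraries 2 and 1 of 12) and 10 and 1 of 12 in the dendritic cell list (10 and 1, camera adjusted p = 0.0513). There were 1 and 0 of 5 in the mast cell and eosinophil list (0 and 0, camera adjusted p = 0.831, without Adipoq-rich libraries 1 and 0 of 4, median -0.81, not 0.62) and 2 and 1 of 7 in the lymphatic endothelial list (2 and 1, camera adjusted p = 0.908). Counts were 8 and 7 of 17 in the smooth muscle and pericyte list (8 and 7, camera adjusted p = 0.314) and 1 and 2 of 13 in the adipocyte list (0 and 2, camera adjusted p = 0.866, median 5.39, mean 3.76, camera direction down, without Adipoq-rich libraries 1 and 3 of 11, median 0.69, not 5.39). There were 5 and 5 of 12 in the Schwann cell and neuron list (5 and 5, camera adjusted p = 0.492) and 0 and 3 of 3 in the erythroid list (0 and 3, camera adjusted p = 0.298). Counts were 5 and 3 of 9 in the atrial cardiomyocyte list (5 and 3, camera adjusted p = 0.104) and 3 and 1 of 5 in the skeletal muscle list (3 and 1, camera adjusted p = 0.407, without Adipoq-rich libraries 7 and 1 of 10). There were 9 and 9 of 23 in the immediate early and heat shock list (9 and 9, camera adjusted p = 0.542, with library size alone 10 and 8 with a median of 0.14) and 11 and 6 of 22 in the ER stress and unfolded protein response list (11 and 6, camera adjusted p = 0.68). Counts were 2 and 4 of 12 in the renin-angiotensin and natriuretic receptors list (2 and 4, camera adjusted p = 0.298, with library size alone 3 and 4 with a median of 0.20, without Adipoq-rich libraries 3 and 7 of 13).

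Over the 14347 genes tested at 7 d against sham, 5571 were higher and 5059 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3322 and 2481 of these differed by at least 2-fold. In 80.8% of genes the 3 libraries of a group lay wholly on one side of the other 3, where chance gives 10%. Among the largest rises, Creg2, Npy, Fam26f and Gjb5 had 0 counts in the sham libraries, and against a floor of 3 counts over the sham group they were at least 75.8-fold, at least 60.3-fold, at least 53.7-fold and at least 45.9-fold higher. Slc1a6 had 2 sham counts and a ratio of 240.4 (95% counting interval 66.3 to 1988), and Scel had 3 and a ratio of 201 (95% counting interval 68.5 to 974). The largest falls were in Scn4b, a sodium channel subunit gene, from 83.5 to 0.646 CPM, and in Clcn1 (log2 FC -5.95 ± 0.43), Fbp2 (-5.81 ± 0.54), Lrtm1 (-5.78 ± 0.76), Efnb3 (-5.77 ± 0.76) and Lgi1 (-5.76 ± 0.74). Camera called 24 of 52 lists higher and 11 lower, and 0 with an estimated correlation, where 11 had an unadjusted p under 0.05. With library size alone the median log2 FC of all genes was 0.39 and not 0.06, and 67.3% of the called genes were higher, against 52.4% with TMM. Clcn1 had a ratio of counts of 0.0085 (0.00174 to 0.0251) without MI 7 d replicate 2. Without sham replicates 1 and 3 Creg2 was at least 50.4-fold and 49.5-fold and Fam26f 35.7-fold and 35.1-fold higher. Gjb5 was then at least 30.5-fold and 30.0-fold and Npy 40.1-fold and 39.4-fold higher. Scel was at a ratio of 400.0 (71.6 to 15814) without sham replicate 1. Slc1a6 was at a ratio of 159.7 (44.1 to 1321) without sham replicate 1.

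The comparison of hearts at 28 d with sham hearts asks what differs 28 d after the artery was tied. At 28 d 15 of 19 genes of the fetal and wall stress programme and 11 of 13 cartilage-like genes were higher than in sham hearts, and all 50 respiratory chain genes were lower. Nppa reached 14479 ± 2910.1 CPM, 28.9-fold above sham, and Nppb rose from 388 ± 13.8 to 908 ± 65.3 CPM (log2 FC 1.23 ± 0.093). Myh7 rose 13.6-fold, while Myh6 fell 2.8-fold and Atp2a2 3.16-fold. Col1a1 was 3.9-fold, Col3a1 4.64-fold, Postn 5.34-fold and Cd68 2.1-fold above sham. Acta2 rose 1.57-fold and Mki67 1.74-fold, and Ppargc1a fell 1.94-fold. Acta1 stood at 1145 ± 295 CPM in sham hearts and 953 ± 938 CPM at 28 d and did not pass (edgeR adjusted p = 0.751). Acta1 passed without MI 28 d replicate 1 (log2 FC -1.48, edgeR adjusted p = 0.00306). Its log2 FC was -1.32 without Adipoq-rich libraries, with MI 28 d replicate 2 alone at 28 d.

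Of the genes for fibrillar collagens and fibril assembly 22 of 26 rose and 2 fell (23 and 2 adjusted over the list alone, camera adjusted p = 4.69e-16, adjusted p = 0.105 with an estimated correlation). Fmod rose 46.2-fold. Of the cross-linking enzymes all 7 rose (7 adjusted over the list alone, camera adjusted p = 5.39e-11, adjusted p = 0.103 with an estimated correlation). Lox was 5.0-fold higher. Among cartilage-like genes of late scar fibroblasts 11 of 13 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 1.7e-13, adjusted p = 0.103 with an estimated correlation). Comp, a cartilage matrix protein gene, rose from 11.8 to 534 CPM and Cilp2 55.1-fold. Of the markers of activated fibroblasts 19 of 20 rose and 1 fell (Lrrc15, log2 FC -3.1), 19 and 1 adjusted over the list alone, camera adjusted p = 1.55e-16, adjusted p = 0.103 with an estimated correlation. For matrix proteases and inhibitors 15 of 25 rose and 5 fell (15 and 5 adjusted over the list alone, camera adjusted p = 0.00235, adjusted p = 0.166 with an estimated correlation). Timp1 was 9.29-fold higher and Mmp13 6.68-fold lower. Of the resting fibroblast markers 10 of 17 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.000202, adjusted p = 0.166 with an estimated correlation). Mgp rose 7.35-fold. Lrrc15 had a log2 FC of -3.71 without MI 28 d replicate 1. Lrrc15 had a log2 FC of -4.69 without Adipoq-rich libraries.

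In TGF-beta signalling 16 of 20 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 8.76e-13, adjusted p = 0.103 with an estimated correlation). For Wnt signalling 12 of 19 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.79e-07, adjusted p = 0.141 with an estimated correlation). Dkk3 rose 29.1-fold. Of the senescence and secretory genes all 14 rose (14 adjusted over the list alone, camera adjusted p = 5.39e-11, adjusted p = 0.103 with an estimated correlation). The stress cytokine gene Gdf15 was 24.6-fold higher. In the fetal and wall stress programme 15 of 19 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 4.5e-20, adjusted p = 0.103 with an estimated correlation). Sprr1a rose from 1.21 to 135 CPM. Among atrial cardiomyocyte markers 6 of 9 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 8.09e-05, adjusted p = 0.12 with an estimated correlation), with Nppa and Dkk3 among the rises, while the atrial myosin light chain gene Myl7, chosen after its values were seen, had at most 1.1 CPM in any library. Of the lymphatic endothelial markers 5 of 7 rose and 1 fell (Prox1, log2 FC -1.23), 6 and 1 adjusted over the list alone, camera adjusted p = 0.0415, adjusted p = 0.335 with an estimated correlation.

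Of the monocyte and macrophage markers 23 of 26 rose and 1 fell (Cx3cr1, log2 FC -0.93), 23 and 1 adjusted over the list alone, camera adjusted p = 7.35e-13, adjusted p = 0.108 with an estimated correlation. Lgals3 rose 27.3-fold. For antigen presentation on MHC class II 8 of 10 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 9.95e-09, adjusted p = 0.12 with an estimated correlation). H2-Ab1 was 3.43-fold higher. Among T and NK cell genes 16 of 22 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 0.000818, adjusted p = 0.263 with an estimated correlation). Ccl5 rose 8.05-fold. In the complement list 17 of 20 rose and 1 fell (Cd59a, log2 FC -0.50), 18 and 1 adjusted over the list alone, camera adjusted p = 1.06e-06, adjusted p = 0.261 with an estimated correlation. Of the interferon-stimulated genes 22 of 26 rose and 1 fell (Rsad2, log2 FC -0.71), 22 and 1 adjusted over the list alone, camera adjusted p = 1.75e-06, adjusted p = 0.103 with an estimated correlation. For chemokines and cytokines 17 of 31 rose and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 0.00408, adjusted p = 0.261 with an estimated correlation). Cd59a did not pass with library size alone (adjusted p 0.0541).

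Of the lysosome and autophagy genes 18 of 26 rose and 3 fell (20 and 3 adjusted over the list alone, camera adjusted p = 0.00048, adjusted p = 0.103 with an estimated correlation). In oxidative stress and ferroptosis 17 of 26 rose and 6 fell (17 and 6 adjusted over the list alone, camera adjusted p = 0.00124, adjusted p = 0.103 with an estimated correlation). For apoptosis and necroptosis 12 of 22 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.00887, adjusted p = 0.311 with an estimated correlation). In the cell cycle list 22 of 40 rose and 1 fell (Cenpf, log2 FC -1.74), 23 and 1 adjusted over the list alone, camera adjusted p = 0.00852, adjusted p = 0.576 with an estimated correlation. Among immediate early and heat shock genes 10 of 23 rose and 6 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.108 with an estimated correlation). Nr4a3 rose 15.5-fold, while Fos fell from 67.2 ± 9.74 to 11.7 ± 3.11 CPM and Fosb fell 4.85-fold. Of the circadian clock genes 12 of 19 rose and 6 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.000713, adjusted p = 0.103 with an estimated correlation). Per2, a repressor of the core clock, rose from 3.62 ± 0.977 to 61.8 ± 18 CPM and Dbp 11.2-fold. Arntl, which encodes the clock activator BMAL1, fell from 51.4 ± 1.87 to 3.43 ± 0.578 CPM and its partner Npas2 fell 5.95-fold. Nr4a3 had a log2 FC of 3.32 without Adipoq-rich libraries.

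**Figure D3:**
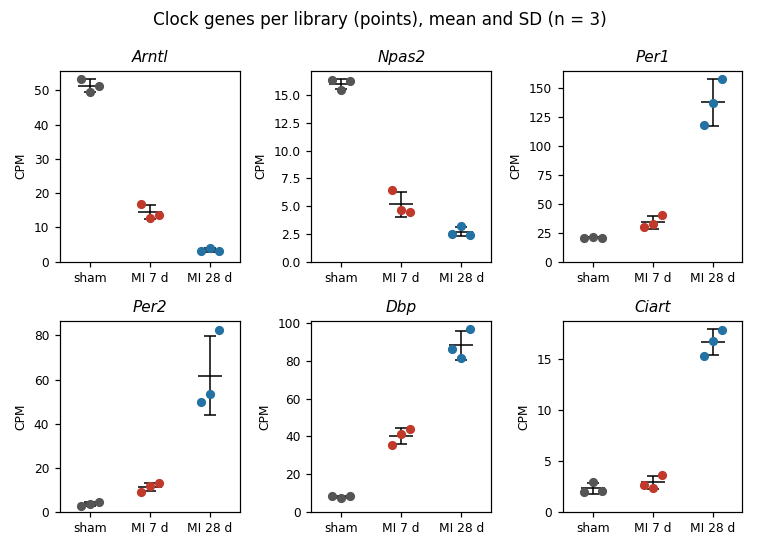
CPM (linear axes) of 6 clock genes in sham, MI 7 d and MI 28 d hearts. Points are single libraries and bars the mean and SD of 3. Arntl stood at 51.4, 14.5 and 3.43 CPM and Dbp at 7.86, 40.2 and 88.1 CPM in the 3 groups.

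In the adult sarcomere list 1 of 30 rose and 18 fell (Des, log2 FC 0.59), 1 and 21 adjusted over the list alone, camera adjusted p = 2.15e-05, adjusted p = 0.498 with an estimated correlation. Tnni3 fell 2.96-fold. Of the calcium handling genes 1 of 20 rose and 12 fell (Fkbp1b, log2 FC 1.55), 1 and 12 adjusted over the list alone, camera adjusted p = 0.00176, adjusted p = 0.386 with an estimated correlation. Among ion channel and gap junction genes 2 of 24 rose and 18 fell (2 and 18 adjusted over the list alone, camera adjusted p = 5.68e-06, adjusted p = 0.281 with an estimated correlation). For adrenergic and cyclic AMP signalling 2 of 16 rose and 8 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.0291, adjusted p = 0.429 with an estimated correlation), against 2 higher and 6 lower with library size alone, where the median was 0.0087. Of the respiratory chain genes all 50 fell (50 adjusted over the list alone, camera adjusted p = 1.3e-23, adjusted p = 0.261 with an estimated correlation). Cox7a1 fell 4.4-fold. In the TCA cycle list all 23 fell (23 adjusted over the list alone, camera adjusted p = 6.35e-13, adjusted p = 0.263 with an estimated correlation). Idh2 was 2.73-fold lower. For fatty acid oxidation 1 of 31 rose and 28 fell (Cpt1a, log2 FC 0.29), 1 and 28 adjusted over the list alone, camera adjusted p = 4.47e-17, adjusted p = 0.204 with an estimated correlation. Acaa2 fell 5.27-fold. Cpt1a did not pass without sham replicate 2 (log2 FC 0.26, edgeR adjusted p = 0.0648).

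In branched-chain amino acid and ketone catabolism 0 of 21 rose and 20 fell (0 and 20 adjusted over the list alone, camera adjusted p = 4.42e-11, adjusted p = 0.261 with an estimated correlation). Among PPAR and PGC-1 regulators 0 of 18 rose and 11 fell (0 and 11 adjusted over the list alone, camera adjusted p = 0.00111, adjusted p = 0.261 with an estimated correlation). Of the endothelial markers 0 of 24 rose and 17 fell (0 and 17 adjusted over the list alone, camera adjusted p = 4.89e-06, adjusted p = 0.32 with an estimated correlation). Kdr fell 4.13-fold and the adhesion gene Cdh5 2.6-fold. Of the mesothelial markers, genes of the outer lining of the heart, all 13 rose (13 adjusted over the list alone, camera adjusted p = 4.51e-05, adjusted p = 0.329 with an estimated correlation). Upk3b stood at 43.7, 52.6 and 293 CPM in MI 28 d replicates 1, 2 and 3, against 0.549 ± 0.33 CPM in sham hearts. Wt1, chosen after its values were seen, stood at 11.5, 11.3 and 107 CPM in the same libraries (log2 FC 2.75 ± 0.96). Adipocyte transcripts were uneven, with Adipoq at 217 CPM in MI 7 d replicate 3, 130 CPM in MI 28 d replicate 1 and 122 CPM in MI 28 d replicate 3, and at most 3.12 CPM in the other 6 libraries. Without these 3 libraries, a setting chosen after seeing the data, MI 28 d replicate 2 is the only library left at 28 d. Values at 28 d then have no replicate, and their spread comes from the other groups. In the resident macrophage list 3 of 13 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.197), without Adipoq-rich libraries 3 and 5 of 11, median -1.14, not 0.96. Among B and plasma cell genes 6 of 13 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.256), without Adipoq-rich libraries 2 and 1 of 12. Wt1 did not pass without sham replicates 1, 2 or 3 (log2 FC 2.72, 2.75 and 2.75, edgeR adjusted p = 0.12, 0.111 and 0.115), nor with no filter (adjusted p 0.0771), with only the libraries compared (0.0627) or with voom (0.0855). Wt1 had a log2 FC of 0.83 without MI 28 d replicate 3, 0.81 without Adipoq-rich libraries and 1.94 with voom.

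**Figure D4:**
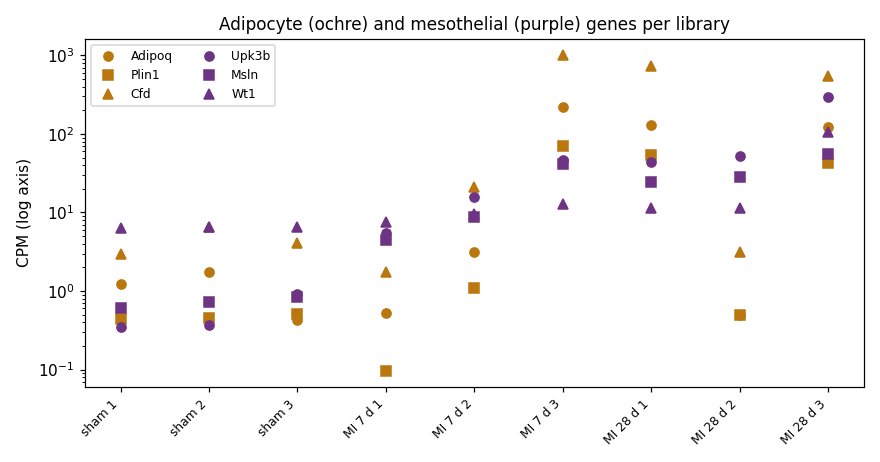
CPM (log axis) of adipocyte and mesothelial genes in each of the 9 libraries, 1 point per gene and library. Adipoq stood at 217, 130 and 122 CPM in MI 7 d replicate 3 and MI 28 d replicates 1 and 3, and Wt1 at 107 CPM in MI 28 d replicate 3.

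Camera did not call the other lists at 28 d against sham. Genes higher and lower are given for each, with those adjusted over the list alone in parentheses. They were 4 and 3 of 16 in the basement membrane list (3 and 2, camera adjusted p = 0.682) and 2 and 0 of 10 in the neutrophil list (2 and 0, camera adjusted p = 0.579, without Adipoq-rich libraries 2 and 0 of 12, median -0.16, not 0.79). Genes higher and lower were 7 and 2 of 12 in the dendritic cell list (7 and 2, camera adjusted p = 0.147) and 0 and 0 of 5 in the mast cell and eosinophil list (0 and 0, camera adjusted p = 0.736, without Adipoq-rich libraries 0 and 0 of 4, median -0.25, not 1.82). There were 7 and 0 of 12 in the inflammasome and pyroptosis list (7 and 0, camera adjusted p = 0.0605) and 8 and 12 of 25 in the glycolysis and glucose uptake list (8 and 12, camera adjusted p = 0.507, with library size alone 9 and 8 with a median of -0.062). Counts were 8 and 11 of 23 in the hypoxia and angiogenesis list (9 and 11, camera adjusted p = 0.172, median 0.32, mean -0.044, camera direction down, without Adipoq-rich libraries 9 and 11, median -0.30, not 0.32) and 7 and 6 of 17 in the smooth muscle and pericyte list (7 and 6, camera adjusted p = 0.929, median -0.17, mean 0.035, camera direction up, with library size alone 8 and 5 with a median of 0.076). There were 0 and 1 of 13 in the adipocyte list (0 and 0, camera adjusted p = 0.507, with library size alone 1 and 0 with a median of 6.32, without Adipoq-rich libraries 1 and 3 of 11, median -0.56, not 6.08) and 4 and 2 of 12 in the Schwann cell and neuron list (4 and 2, camera adjusted p = 0.323, median -0.17, mean 0.69, camera direction up, with library size alone 4 and 2 with a median of 0.088). Counts were 0 and 2 of 3 in the erythroid list (0 and 3, camera adjusted p = 0.146) and 2 and 0 of 5 in the skeletal muscle list (2 and 0, camera adjusted p = 0.453, median -0.16, mean 1.19, camera direction up, with library size alone 2 and 0 with a median of 0.084, without Adipoq-rich libraries 2 and 1 of 10, median 1.41, not -0.16). There were 7 and 5 of 22 in the ER stress and unfolded protein response list (7 and 5, camera adjusted p = 0.736, without Adipoq-rich libraries 5 and 9, median -0.17, not 0.13) and 2 and 4 of 12 in the renin-angiotensin and natriuretic receptors list (2 and 4, camera adjusted p = 0.558, median 0.053, mean 0.17, camera direction down, without Adipoq-rich libraries 3 and 4 of 13, median -0.25, not 0.053). Counts were 11 and 1 of 39 in the cytosolic ribosomal proteins list (7 and 1, camera adjusted p = 0.172, without Adipoq-rich libraries 4 and 1).

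Over all genes tested at 28 d against sham, 4204 were higher and 3656 lower by edgeR's quasi-likelihood test, 1979 and 1017 of them by at least 2-fold. No overlap between the groups was seen in 66.4% of genes, where chance gives 10% with equal spread and more with the less variable sham libraries. Gjb5 had 0 sham counts and was at least 53.8-fold higher. With 2 sham counts each, the ratio of counts was 408 (95% counting interval 113 to 3373) for the chemokine gene Cxcl13, 320.2 (95% counting interval 88.4 to 2648) for Vat1l and 269 (95% counting interval 74.1 to 2223) for Gata5. Col6a5 also led the rises (log2 FC 8.17 ± 1.96). The largest falls were in Clcn1 (log2 FC -4.94 ± 0.40), Lingo3 (-3.97 ± 0.28), Arntl (-3.9 ± 0.15), Cyp1a1 (-3.77 ± 0.40), Scn4b (-3.69 ± 0.78) and Kcnv2 (-3.52 ± 0.37). Camera called 25 of 52 lists higher and 10 lower, and 0 with an estimated correlation, where 16 had an unadjusted p under 0.05. With library size alone the median log2 FC of all genes was 0.29 and not 0.05, and 73.8% of the called genes were higher, against 53.5% with TMM. With the sham libraries summed to 1 sample fewer genes passed, but the sham group then had no replicate. Col6a5 had a log2 FC of 6.18 without MI 28 d replicate 3. Cxcl13 did not pass without sham replicates 1, 2 or 3 or MI 28 d replicates 1 or 3 (edgeR adjusted p = 0.127, 0.115, 0.121, 0.0918 and 0.136), nor with no filter (adjusted p 0.0735) or with voom (0.254). Cxcl13 was at a ratio of 271 (74.9 to 2242) without sham replicate 1 and at a ratio of 229.5 (63.1 to 1902) without MI 28 d replicate 3. Cyp1a1 had a log2 FC of -4.37 without MI 28 d replicate 3. Gata5 was at a ratio of 179 (49.3 to 1477) without sham replicate 1 and at least 117-fold higher without sham replicate 3 and at a ratio of 52.6 (14.2 to 440.5) without MI 28 d replicate 3. Gjb5 was at least 35.8-fold and 35.2-fold higher without sham replicates 1 and 3 and at least 21.5-fold higher without MI 28 d replicate 3. Scn4b had a log2 FC of -5.41 without MI 28 d replicate 1. Vat1l did not pass without sham replicates 1, 2 or 3 (edgeR adjusted p = 0.0709, 0.0629 and 0.0666). Vat1l was at a ratio of 213 (58.7 to 1759.7) without sham replicate 1 and at a ratio of 37.8 (10.1 to 318) without MI 28 d replicate 3. Col6a5 did not pass with voom (adjusted p 0.0798). Without Adipoq-rich libraries the log2 FC was 6.02 for Col6a5, -4.74 for Cyp1a1 and -6.01 for Scn4b. With voom the log2 FC was 7.16 for Col6a5 and -4.5 for Scn4b. Without the Adipoq-rich libraries the ratio was 12.7 (2.83 to 117) for Cxcl13, 43.5 (11.3 to 371) for Gata5, at least 26.8-fold for Gjb5 and 29.7 (7.48 to 257) for Vat1l.

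The direct comparison of hearts at 28 d with hearts at 7 d asks which genes differ between the early and the late time, in different mice. At 28 d 25 of 26 monocyte and macrophage markers, 21 of 26 collagen and fibril genes and 34 of 40 cell cycle genes were lower than at 7 d. All 30 genes of the sarcomere list and all 50 respiratory chain genes were higher. Col1a1 fell 8.91-fold from 11892 ± 2014 to 1335 ± 307 CPM, Col3a1 5.15-fold, Postn 7.55-fold, Cd68 9.23-fold, Acta2 2.18-fold and Mki67 3.15-fold. Myh6 rose 3.45-fold, Atp2a2 3.37-fold and Ppargc1a 4.12-fold. Myh7 rose 3.29-fold, Nppb 2.33-fold (log2 FC 1.22 ± 0.093), Nppa 1.58-fold and Acta1 4.48-fold. Acta1 did not pass without MI 7 d replicates 2 or 3 (log2 FC 2.03 and 2.06, edgeR adjusted p = 0.079 and 0.0767), nor with no filter (adjusted p 0.0528), with only the libraries compared (0.065) or with voom (0.0703). Acta1 had a log2 FC of 0.95 without MI 28 d replicate 1. Nppa did not pass without MI 7 d replicate 3 or MI 28 d replicate 2 (log2 FC 0.50 and 0.51, edgeR adjusted p = 0.0703 and 0.0665), nor with only the libraries compared (adjusted p 0.0504). Acta1 had a log2 FC of 1.01 without Adipoq-rich libraries.

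Of the genes for fibrillar collagens and fibril assembly 2 of 26 rose and 21 fell (2 and 21 adjusted over the list alone, camera adjusted p = 3.75e-18, adjusted p = 0.158 with an estimated correlation). The fibronectin gene Fn1 was 8.66-fold lower. Among cross-linking enzymes 1 of 7 rose and 6 fell (Tgm2, log2 FC 0.31), 1 and 6 adjusted over the list alone, camera adjusted p = 3.44e-06, adjusted p = 0.158 with an estimated correlation. For matrix proteases and inhibitors 3 of 25 rose and 14 fell (3 and 14 adjusted over the list alone, camera adjusted p = 2.02e-07, adjusted p = 0.0614 with an estimated correlation). Mmp12 fell 19.6-fold. Of the markers of activated fibroblasts 1 of 20 rose and 16 fell (Thbs4, log2 FC 0.58), 1 and 16 adjusted over the list alone, camera adjusted p = 4.74e-12, adjusted p = 0.158 with an estimated correlation, with Cthrc1 19.7-fold and Tnc 14.8-fold lower. In the basement membrane list 3 of 16 rose and 10 fell (3 and 11 adjusted over the list alone, camera adjusted p = 0.0059, adjusted p = 0.346 with an estimated correlation). For TGF-beta signalling 2 of 20 rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.405 with an estimated correlation). Of the senescence and secretory genes 2 of 14 rose and 10 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.0306, adjusted p = 0.405 with an estimated correlation). Of the cartilage-like genes 4 of 13 rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.526). Acan was 21.3-fold lower and Cytl1 9.32-fold higher. Tgm2 did not pass without MI 7 d replicate 2 or MI 28 d replicate 2 (log2 FC 0.25 and 0.29, edgeR adjusted p = 0.067 and 0.0579), nor with library size alone (adjusted p 0.063) or with only the libraries compared (0.0901). Thbs4 did not pass without MI 7 d replicates 1 or 3 or MI 28 d replicates 1 or 2 (log2 FC 0.45, 0.60, 0.67 and 0.32, edgeR adjusted p = 0.147, 0.0844, 0.0607 and 0.157), nor with library size alone (adjusted p 0.0904), with no filter (0.0716), with only the libraries compared (0.0926) or with voom (0.0577).

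Of the monocyte and macrophage markers 0 of 26 rose and 25 fell (0 and 26 adjusted over the list alone, camera adjusted p = 1.08e-39, adjusted p = 0.0534 with an estimated correlation). Spp1 fell from 425 ± 64.9 to 17.3 ± 5.25 CPM and the protease gene Ctss 13.2-fold. In the lysosome and autophagy list 7 of 26 rose and 17 fell (7 and 17 adjusted over the list alone, camera adjusted p = 3.59e-08, adjusted p = 0.0534 with an estimated correlation). Of the neutrophil markers 0 of 10 rose and 7 fell (0 and 7 adjusted over the list alone, camera adjusted p = 0.0146, adjusted p = 0.405 with an estimated correlation), without Adipoq-rich libraries 0 and 3 of 12. For antigen presentation on MHC class II 0 of 10 rose and 8 fell (0 and 8 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.405 with an estimated correlation). Among T and NK cell genes 1 of 22 rose and 10 fell (Ctla4, log2 FC 2.09), 1 and 9 adjusted over the list alone, camera adjusted p = 0.0174, adjusted p = 0.405 with an estimated correlation. In the chemokine and cytokine list 0 of 31 rose and 13 fell (0 and 13 adjusted over the list alone, camera adjusted p = 0.00598, adjusted p = 0.346 with an estimated correlation). For complement 2 of 20 rose and 6 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.0234, adjusted p = 0.56 with an estimated correlation), with a median log2 FC of 0.12, a mean of -0.10 and a camera direction of down, without Adipoq-rich libraries 6 and 9 of 19, median -0.41, not 0.12. C7 was 8.91-fold higher. Of the resident macrophage markers 2 of 13 rose and 3 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.8). Timd4 had a log2 FC of 2.83 ± 0.83. Without the 3 Adipoq-rich libraries, with MI 28 d replicate 2 alone at 28 d, the list median was -0.63, not 1.4, and Timd4 had -0.24. C7 had a log2 FC of 3.81 without MI 7 d replicate 3. Timd4 did not pass without MI 7 d replicates 1 or 3 (log2 FC 2.67 and 2.79, edgeR adjusted p = 0.0597 and 0.0549), nor with voom (adjusted p 0.113). Timd4 had a log2 FC of 1.59 without MI 28 d replicate 3. Timd4 had a log2 FC of 2.09 with voom.

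For inflammasome genes 1 of 12 rose and 10 fell (Txnip, log2 FC 0.71), 1 and 10 adjusted over the list alone, camera adjusted p = 0.00093, adjusted p = 0.158 with an estimated correlation. Of the apoptosis and necroptosis genes 2 of 22 rose and 18 fell (2 and 18 adjusted over the list alone, camera adjusted p = 0.000106, adjusted p = 0.243 with an estimated correlation). In oxidative stress and ferroptosis 8 of 26 rose and 12 fell (9 and 13 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.292 with an estimated correlation). Among cell cycle genes 3 of 40 rose and 34 fell (4 and 34 adjusted over the list alone, camera adjusted p = 5.22e-08, adjusted p = 0.346 with an estimated correlation). The cyclin gene Ccnb2 was 5.24-fold lower and Ccnd2 2.63-fold higher. Of the ribosomal protein genes 0 of 39 rose and 37 fell (0 and 38 adjusted over the list alone, camera adjusted p = 1.79e-07, adjusted p = 0.474 with an estimated correlation), with a median log2 FC of -0.54. In the immediate early and heat shock list 15 of 23 rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 0.000421, adjusted p = 0.0614 with an estimated correlation). For the circadian clock 16 of 19 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 4.31e-06, adjusted p = 0.0614 with an estimated correlation). Hlf was 6.96-fold higher. Txnip did not pass without MI 7 d replicate 2 (log2 FC 0.63, edgeR adjusted p = 0.0513).

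In the adult sarcomere list all 30 rose (30 adjusted over the list alone, camera adjusted p = 8.48e-18, adjusted p = 0.346 with an estimated correlation). Hrc, a calcium-binding protein gene of the sarcoplasmic reticulum, rose 6.44-fold. Of the calcium handling genes 17 of 20 rose and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 4.23e-07, adjusted p = 0.346 with an estimated correlation). Among ion channel and gap junction genes 20 of 24 rose and 1 fell (Gja5, log2 FC -1.16), 21 and 1 adjusted over the list alone, camera adjusted p = 4.64e-07, adjusted p = 0.346 with an estimated correlation. For adrenergic and cyclic AMP signalling 11 of 16 rose and 1 fell (Grk2, log2 FC -0.38), 11 and 1 adjusted over the list alone, camera adjusted p = 0.000963, adjusted p = 0.346 with an estimated correlation. Of the respiratory chain genes all 50 rose (50 adjusted over the list alone, camera adjusted p = 3.34e-20, adjusted p = 0.346 with an estimated correlation). Cox7a1 was 4.71-fold higher. In the TCA cycle list all 23 rose (23 adjusted over the list alone, camera adjusted p = 2.38e-14, adjusted p = 0.346 with an estimated correlation).

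For fatty acid oxidation 29 of 31 rose and 1 fell (Cpt1a, log2 FC -0.45), 29 and 1 adjusted over the list alone, camera adjusted p = 3.03e-10, adjusted p = 0.362 with an estimated correlation. In branched-chain amino acid and ketone catabolism all 21 rose (21 adjusted over the list alone, camera adjusted p = 8.02e-08, adjusted p = 0.405 with an estimated correlation). Bdh1 rose 10.4-fold. Among PPAR and PGC-1 regulators 11 of 18 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 3.73e-05, adjusted p = 0.327 with an estimated correlation). In glycolysis and glucose uptake 18 of 25 rose and 2 fell (18 and 3 adjusted over the list alone, camera adjusted p = 0.000167, adjusted p = 0.346 with an estimated correlation). Vegfa rose 3.21-fold, in a list of hypoxia and angiogenesis genes of which 9 of 23 rose and 5 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.434).

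Camera did not call the other lists at 28 d against 7 d. Genes higher and lower are given for each, with those adjusted over the list alone in parentheses. They were 5 and 7 of 17 in the resting fibroblast list (5 and 8, camera adjusted p = 0.757, median -0.085, mean 0.28, camera direction down) and 3 and 5 of 19 in the Wnt signalling list (2 and 5, camera adjusted p = 0.256, median 0.07, mean 0.061, camera direction down, without Adipoq-rich libraries 3 and 7, median -0.31, not 0.07). Genes higher and lower were 1 and 2 of 13 in the B and plasma cell list (1 and 1, camera adjusted p = 0.914) and 1 and 5 of 12 in the dendritic cell list (0 and 5, camera adjusted p = 0.0783, without Adipoq-rich libraries 2 and 3). There were 0 and 1 of 5 in the mast cell and eosinophil list (0 and 1, camera adjusted p = 0.987, median 1.23, mean 0.85, camera direction down, without Adipoq-rich libraries 1 and 1 of 4, median -0.15, not 1.23) and 0 and 8 of 26 in the interferon-stimulated list (0 and 6, camera adjusted p = 0.42, without Adipoq-rich libraries 7 and 8, median 0.032, not -0.017). Counts were 10 and 4 of 19 in the fetal gene and wall stress programme list (10 and 4, camera adjusted p = 0.118) and 5 and 2 of 24 in the endothelial list (4 and 1, camera adjusted p = 0.845, median -0.044, mean 0.11, camera direction up, with library size alone 4 and 5 with a median of -0.14, without Adipoq-rich libraries 10 and 1, median 0.25, not -0.044). There were 5 and 0 of 7 in the lymphatic endothelial list (5 and 0, camera adjusted p = 0.0979) and 2 and 6 of 17 in the smooth muscle and pericyte list (2 and 6, camera adjusted p = 0.118). Counts were 1 and 1 of 13 in the epicardial and mesothelial list (0 and 1, camera adjusted p = 0.434, without Adipoq-rich libraries 6 and 1) and 2 and 0 of 13 in the adipocyte list (2 and 0, camera adjusted p = 0.395, without Adipoq-rich libraries 3 and 0 of 11, median -0.25, not 0.61). There were 2 and 3 of 12 in the Schwann cell and neuron list (1 and 3, camera adjusted p = 0.799, median 0.50, mean -0.12, camera direction down, without Adipoq-rich libraries 1 and 5) and 0 and 0 of 3 in the erythroid list (0 and 0, camera adjusted p = 0.791). Counts were 4 and 1 of 9 in the atrial cardiomyocyte list (4 and 2, camera adjusted p = 0.414) and 2 and 2 of 5 in the skeletal muscle list (2 and 2, camera adjusted p = 0.526, without Adipoq-rich libraries 1 and 2 of 10). There were 5 and 5 of 22 in the ER stress and unfolded protein response list (5 and 5, camera adjusted p = 0.799, without Adipoq-rich libraries 3 and 11) and 4 and 2 of 12 in the renin-angiotensin and natriuretic receptors list (4 and 2, camera adjusted p = 0.251).

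Over all genes tested at 28 d against 7 d, 4141 were higher and 3744 lower by edgeR's quasi-likelihood test, 1382 and 1580 of them by at least 2-fold, and 59.8% of genes had no overlap between the groups, where chance gives 10% with equal spread. The largest rises were in Retnla (log2 FC 5.79 ± 1.21), Inmt (4.33 ± 0.64), Lrtm1 (3.77 ± 0.70), Ppl (3.62 ± 0.89), Edn3 (3.59 ± 0.68) and Ache (3.59 ± 0.24). The largest falls were in Stra6l (-6.09 ± 0.53), Cemip (-5.82 ± 0.34), C1qtnf3 (-5.62 ± 0.45), Npy (-5.58 ± 0.63), Adamts16 (-5.58 ± 0.48) and Col11a1 (-4.89 ± 0.44). Camera called 12 of 52 lists higher and 19 lower, and 0 with an estimated correlation, where 10 had an unadjusted p under 0.05. More genes were lower than higher with library size alone (4123 and 3444) or only the libraries compared (3557 and 3122). The main test also uses the smaller sham spread. Fry, which does not compare a list with other genes, called 46, 40 and 39 lists in the 3 comparisons. Inmt had a log2 FC of 5.64 without MI 7 d replicate 3 and 3.69 without MI 28 d replicate 3. Lrtm1 had a log2 FC of 2.53 without MI 28 d replicate 1. Npy had a ratio of counts of 0.00606 (0.000153 to 0.034) without MI 28 d replicate 3. Ppl had a log2 FC of 2.15 without MI 28 d replicate 3. Retnla had a log2 FC of 6.92 without MI 7 d replicate 3 and 4.63 without MI 28 d replicate 3. Stra6l had a log2 FC of -5.49 without MI 28 d replicate 3. Stra6l had a ratio of counts of 0.00792 (0.000957 to 0.0288) without MI 28 d replicate 1. Retnla did not pass with voom (adjusted p 0.144). Without Adipoq-rich libraries the log2 FC was 2.55 for Lrtm1, 2.77 for Ppl and 3.78 for Retnla. Without the Adipoq-rich libraries the ratio was 0.00302 (7.64e-05 to 0.0169) for Adamts16.

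Of the genes called against sham, 3608 were higher and 3253 lower at both times, and 166 of the 7027 called in both moved in opposite directions. Simulated unchanged groups sharing the sham libraries gave a mean of 0.1 genes and at most 1 in either direction over 20 simulations, and independent lists of these sizes would share 1632 and 1289. Across genes, which are not independent replicates, the log2 FCs at 7 d and 28 d had a correlation of 0.836, against a mean of 0.529 in the simulations, and a covariance of 1.61 against 0.0483, a difference of 1.56. The sham group cannot be split. The simulations gave all 3 groups the same spread per gene, and so more noise than the sham libraries showed. Their correlation and covariance are therefore not those of the real spreads. They hold no shift common to the sham group, which may add to the excess. The sham libraries also differed less from each other than the MI libraries did. Values of Hspa1a and Hspa1b, C4b, Myh6 and Myh7 and ribosomal protein genes are uncertain where reads were shared with near-identical copies, as are those of overlapping and antisense genes, since the strand and multi-mapping settings are not given in the sources used here.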

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

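The tests of chance splits were planned before the data were examined, and the tests with voom and the genes named here were chosen after the results were seen. The MI groups differed in their effect against the same sham libraries: by edgeR's quasi-likelihood test of the difference, 4141 genes were higher and 3744 lower at 28 d than at 7 d. Of 166 genes past the threshold in opposite directions at the 2 times, a choice that all but fixes a difference between them, 162 had a mean of at least 1 log2 CPM and a symbol of neither the Gm nor the Rik form. Ache, the acetylcholinesterase gene, had a log2 fold change of -0.73 at 7 d and 2.86 at 28 d, a difference of 3.59. Msc went from 2.82 to -0.70, a difference of -3.52, and Slc37a2 from 2.76 to -0.55, a difference of -3.31. Cytl1 went from -1.58 to 1.64, a difference of 3.22. Ache at 7 d against sham did not pass without sham replicate 1 or MI 7 d replicate 2 (log2 fold change -0.46 and -0.59, edgeR adjusted p = 0.139 and 0.0833), nor with library size alone (adjusted p 0.191) or with voom (0.0697). Slc37a2 at 28 d against sham did not pass without sham replicates 1, 2 or 3 or MI 28 d replicate 3 (log2 fold change -0.56, -0.54, -0.57 and -0.36, edgeR adjusted p = 0.0724, 0.0777, 0.0711 and 0.0935), nor with library size alone (adjusted p 0.166) or with voom (0.0763). Cytl1 at 7 d against sham did not pass with voom (adjusted p 0.0532). Msc at 28 d against sham did not pass with library size alone (adjusted p 0.0687) or with voom (0.164).

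The libraries of 2 groups can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each comparison only 1 of the 10 splits, the real one, gave as many genes as it did. For 7 d against sham the real split gave 10630 genes and the highest other 0, for 28 d against sham 7860 and 0, and for 28 d against 7 d 7885 and 58.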

How the results depend on the processing

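The alternatives without the 3 Adipoq-rich libraries, with the sham libraries summed to 1 and with limma voom were chosen after seeing the data, and the others were planned. Counts of genes higher and lower kept within 1.5 times of 5571 and 5059 (7 d against sham), 4204 and 3656 (28 d against sham) and 4141 and 3744 (28 d against 7 d) with DESeq2, DESeq2-type size factors, no filter, the stricter filter, only the libraries compared, voom and, for 7 d against sham, without the Adipoq-rich libraries (no replicate at 28 d). DESeq2 gave 5547 and 5235, 3934 and 3868, and 4076 and 3658. Leaving out 1 library gave 5118 to 5368 and 4753 to 4961 genes at 7 d, 3296 to 4321 and 3171 to 3824 at 28 d, and 3689 to 4285 and 3260 to 4227 between the MI groups. An added 2-fold threshold gave fewer genes by construction, 3322 and 2481, 1979 and 1017, and 1382 and 1580, with 1693 higher and 915 lower at both times. With library size alone 6437 genes were higher and 2282 lower at 28 d against sham, and 5576 higher and 2034 lower at both times, and the cause was not tested. With the sham libraries summed to 1, which leaves fewer samples, 1860 and 1894 genes passed at 28 d and 1693 and 1758 at both times, and the calls of Ache, Acta1, P4ha2, Rps2 and Upk3b at 7 d against sham and Adamts4, Cd59a, Col6a5, Cpt1a, Cxcl13, Des, Gata5, Hlf, Mki67, Msc, Rsad2, Scn4b, Slc37a2, Vat1l and Wt1 at 28 d against sham were lost. With an estimated correlation camera called 0 lists in each direction and comparison, where the preset correlation called 24 and 11, 25 and 10, and 12 and 19. Leaving out 1 library moved the correlation of fold changes from 0.836 to between 0.796 (without MI 7 d replicate 3) and 0.842, with 0.815 without MI 28 d replicate 2, and the cause was not tested.

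With the replicate number as a block 5507 and 5014, 4044 and 3600, and 4093 and 3653 genes passed. Same-numbered libraries had correlated deviations of 0.021, -0.00203 and -0.00236 between sham and 7 d, 0.00859, -0.0222 and -0.0245 between sham and 28 d, and -0.0909, 0.262 and 0.304 between 7 d and 28 d. In 4 of 9 cases a library correlated best with its own number, too few cases to decide on pairing. With the block the edgeR adjusted p was 0.088 for Cxcl13 and 0.0838 for Wt1 at 28 d against sham and 0.0596 for Thbs4 at 28 d against 7 d, and other named genes kept their calls.

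Of the genes that the rule names, P4ha2 (0.0956) and Csf1 (0.0269) at 7 d and Csf1 (0.00438) at 28 d had a log2 fold change above 0 with library size alone, as had Rps2 at 7 d (0.000115), and Timd4 at 28 d against 7 d had -0.24 without the Adipoq-rich libraries. Library size alone changes 1 factor per library, and why Timd4 changed was not tested. For the genes named in the text 2868 alternative values kept direction and side of the threshold, 96 no longer passed, 3 newly passed, 8 moved and 3 reversed. Over all 740 gene values that the rule names, 11047 alternative values kept direction and side of the threshold, 466 no longer passed, 3 newly passed, 8 moved and 5 reversed. TMM without mitochondrial and haemoglobin genes removed 0 tested genes and gave no value. The depth of 12351525 counts in the shallowest library limits low genes, as for those with 0 to 3 sham counts.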

Other observations

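All tests and genes in this part were chosen only after the results were seen. Among genes past the threshold in opposite directions at the 2 times, the fractalkine receptor gene Cx3cr1 had a log2 fold change of 2.2 at 7 d and -0.93 at 28 d, and the protease gene Adamts4 1.84 and -1.02. The clock output gene Hlf went from -2.0 to 0.80 and Prg4, which encodes lubricin, from -0.99 to 1.34. The immediate early gene Fos stood at 67.2, 15.5 and 11.7 CPM in sham, 7 d and 28 d hearts. Over all 9 libraries the lung gene Sftpc had 1 count, and the atrial genes Myl7 and Sln had 43 and 8 counts. Hlf at 28 d against sham did not pass without sham replicate 1 (log2 fold change 0.76, edgeR adjusted p = 0.0581). Its log2 fold change was 0.53 without Adipoq-rich libraries, with MI 28 d replicate 2 alone at 28 d.

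Core clock genes moved apart at 28 d: all 10 genes of the arm with Per1 and Dbp rose, with a median log2 fold change of 1.99, and all 4 of the arm with Arntl fell, with a median of -2.07. If sarcomere genes track the share of cardiomyocyte RNA, a lower share as only cause would widen this gap where they are lower. Yet from 7 d to 28 d the gap per library rose by 1.76 (standard error between libraries 0.283). The sarcomere median went from -2.08 to -0.61. A different time of day at collection may give the gap, 4.06 at 28 d and 2.28 at 7 d. A clock altered by the injury would give it too, and the labels give no time of day, so these cannot be told apart.

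Adipocyte genes were high in MI 7 d replicate 3 and MI 28 d replicates 1 and 3, with Car3 at 1171, 761 and 721 CPM and at most 23.7 CPM elsewhere. Fat tissue attached to those hearts is a candidate source, since 10 of 12 other adipocyte genes, all but Cidea and Pnpla2, had their 3 highest values in the same libraries. In the other MI libraries, MI 7 d replicates 1 and 2 and MI 28 d replicate 2, the median log2 ratio to sham was -0.785, 1.07 and -0.458 for adipocyte genes, several of them near the floor, and 2.87, 3.42 and 4.44 for mesothelial genes. Fat that formed in part of the hearts, or that came with part of the mesothelial RNA, was not tested and stays open.

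Sarcomere genes had log2 fold changes at 7 d from -4.96 for Ckm to 0.03 for Des, which did not pass.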
